A study of Homo sapiens with 8 samples.

How the data were processed

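Total RNA from primary human aortic smooth muscle cells was sequenced in 8 libraries, 4 from cells given HPbCD and 4 from cells given phosphate-buffered saline. Per the labels' protocols, libraries were made with the NEBNext Ultra RNA kit and read as 51-base pairs on a NovaSeq 6000. The submitters' processing notes name Salmon 0.14.0, FastQC and GRCh38; the annotation release, the strand setting and the Salmon options are not given in the sources used here. Salmon assigns read pairs to transcripts without a full alignment and shares pairs that fit several transcripts by a likelihood model, so genes with near-identical copies or shared exons have less certain values.

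Each library's deposited table gives, per the file headers, an estimated count of fragments (expected counts, not normalized), a TPM value and an effective length for every transcript. The deposited TPM values are relative transcript abundances, scaled by effective length to a fixed sum within a library. Of 199658 transcript identifiers, 199415 (99.88%) matched GENCODE 29 after the version suffix was dropped; the unmatched ones held 0.021% to 0.028% of the fragments of a library and were left out. Estimated counts were summed over the transcripts of each gene and rounded to whole numbers, and TPM values were summed likewise. All coordinates are those of GENCODE 29 on GRCh38. Totals of 25.2 to 33.7 M fragments per library limit the precision for genes near the expression filter. Fragment length was read from the difference between transcript length and effective length.

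Groups and replicate numbers came from the sample titles. The main test was edgeR 4.0.16 in R 4.3.3 with TMM factors, the default expression filter with group, and the quasi-likelihood F test between the groups, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The quasi-likelihood fit used the method of edgeR 4, while the installed function defaults to the older method, which was run as an alternative. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F and are approximate. CPM values were scaled by TMM factors and are means ± SD over the 4 libraries of a group. No covariate was used.

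Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 34 of 36 lists that had at least 3 tested members. Library composition was compared by exact permutation of the absolute difference of means over all 70 arrangements, adjusted over 3 planned measures; fragment length was added after seeing the data (p = 0.657), and adjusting over 4 measures gives 0.0572 for the mitochondrial share and for the total. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took 12 fixed genes, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members with the lowest p-values of each list described with examples; Y-linked genes and XIST were left out. Some genes that it picks are not reported here. The others were 87 tested genes, and 19 more were named after their values were seen. Which 20 lists were described with examples was also chosen after the results were seen; the other 16 are given as medians and tests.

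The test was checked on simulated counts drawn for the real genes from their means and the library sizes, with 200 genes changed, for the comparison of HPbCD with control. Of 15216 simulated genes tested, 7 of 165 calls (4.2%) were false. Recovery was 52% of genes changed 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 95.7% at 4-fold. These shares were obtained with 200 changed genes, whereas 4725 of 15400 genes were called in the real data, so they may differ there. Of 100 random unchanged lists, 3 had a camera p under 0.05. Each simulated gene was drawn independently, so neither check covers deviations shared between genes. In the real lists the estimated correlation reached 0.76, for the interferon response. Chi-square values per degree of freedom between libraries of a group ran from 2.09 to 26.9, so no pair agreed within sampling noise.

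Alternatives covered scaling (DESeq2 size factors, library size, upper quartile), filters, DESeq2 1.42.0, limma-voom, other edgeR settings, an offset for effective length, log2(TPM + 1) and log2(TPM + 0.1) in limma, the replicate number as a block, and each library left out. Transcript-level comparisons were left out because the annotation release is not known.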

Results

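Bulk RNA sequencing measured the transcriptome of primary human aortic smooth muscle cells, the contractile cells of the aortic wall grown in culture, after exposure to 2-hydroxypropyl-β-cyclodextrin (HPbCD). HPbCD is a ring of glucose units whose hydrophobic cavity holds cholesterol, and it is used to draw cholesterol out of cells. One group received HPbCD at 10 mg/mL and the control group received phosphate-buffered saline, each for 24 h, in cells at passage 5 and 80% confluence. Each group held 4 libraries. Estimated fragment totals ran from 28795563 to 33684103 in the control libraries and from 25161470 to 28344152 in the HPbCD libraries. The labels do not say whether the libraries came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Control replicate 2 stood apart from the other controls: its sequenced fragments averaged 288 bases, against 349 to 363 bases in the other 7 libraries.

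The comparison asks which transcripts HPbCD changes in vascular smooth muscle cells, with particular interest in TFEB, a transcription factor that drives lysosomal genes. HPbCD raised transcripts of cholesterol synthesis and uptake and lowered ABCA1, the membrane transporter that exports cholesterol. Of 15400 genes tested, 4725 (30.7%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test; 2471 rose and 2254 fell. At least 2-fold changes were found for 452 of them, of which 308 rose and 144 fell. The 4 values of each group did not overlap for 33.4% of the tested genes, where chance gives 2.86%. Without control replicate 2, 6000 genes changed, 490 of them at least 2-fold.

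The largest rise among well-expressed genes was that of FABP3, which encodes a fatty acid binding protein of heart and muscle (chromosome 1, 31365625 to 31376850, GRCh38). FABP3 went from 1.38 ± 0.228 to 170.1 ± 8.29 CPM (counts scaled to library size; SD, n = 4 in each group, as for all CPM values), a log2 fold change of 6.94 ± 0.09 (SE). TMEM97, a sterol-responsive membrane protein, rose from 6.50 ± 0.735 to 193.1 ± 6.91 CPM, and the sterol reductase gene TM7SF2 rose from 3.15 ± 0.407 to 75.1 ± 1.85 CPM. Among the largest rises were also those of MVD, ACAT2, HMGCS1 and DHCR7, which encode enzymes of cholesterol synthesis and rose by 3.71 to 3.95 on the log2 scale.

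In the cholesterol synthesis list, 19 of the 20 tested enzymes rose, also 19 adjusted over the list alone, and the median log2 fold change was 3.23. FDPS, which makes farnesyl diphosphate, rose by 3.46 on the log2 scale and DHCR7, which makes cholesterol from its last precursor, rose 13.1-fold. The remaining enzyme, PMVK, had a log2 fold change of 0.16 ± 0.08 and an edgeR adjusted p of 0.165; it was named after its values were seen, and without control replicate 1 its adjusted p was 0.013, in a range of 0.013 to 0.284 over all settings. The list was higher than other genes in the camera test (adjusted p = 1.91e-31, and 0.00286 with an estimated correlation). ACAT2 overlaps TCP1 on the opposite strand and TM7SF2 overlaps VPS51 on the same strand. Here and below, overlap was read from the start and end of each gene, and shared exons were not checked. The strand setting of the library kit is not stated, so reads of such pairs may be divided imprecisely, although TCP1 and VPS51 themselves had log2 fold changes of -0.18 and -0.03.

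Genes of sterol uptake and of the SREBP pathway, which senses low membrane cholesterol, also rose: 7 of 10 passed, over all genes and adjusted over the list alone, with a median of 1.98. INSIG1, the sterol-sensing brake on SREBP processing, rose 12.7-fold from 23.1 ± 1.52 to 293 ± 8.49 CPM. In the fatty acid synthesis list, 11 of 12 genes rose, over all genes and adjusted over the list alone, with a median of 1.64. SCD, the stearoyl-CoA desaturase, went from 164.8 ± 7.14 to 1626 ± 34.2 CPM, and ACSS2, which makes acetyl-CoA from acetate, rose 7.01-fold. The desaturase genes FADS1 and FADS2 rose 7.26-fold and 8.45-fold. They overlap each other on opposite strands, so their separate values may be uncertain. MID1IP1 was the list member that missed the threshold, at a log2 fold change of 0.09 ± 0.05, and was named after its values were seen. Both lists passed camera, at adjusted p values of 1.37e-08 and 3.51e-15, and with an estimated correlation at 0.00871 and 0.00286.

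ABCA1 (chromosome 9, 104781002 to 104928237) showed the largest fall of any well-expressed gene, from 188.7 ± 5.79 to 15.9 ± 1.35 CPM, 11.8-fold lower. It belongs to a list of targets of the liver X receptors, nuclear receptors that respond to oxysterols, in which 6 of 10 tested members fell and 1 rose, over all genes and adjusted over the list alone. MYLIP, which encodes a ubiquitin ligase, fell from 25.1 ± 0.964 to 6.39 ± 0.909 CPM, and the cholesterol exporter ABCG1 fell from 2.60 ± 0.564 to 0.290 ± 0.105 CPM. APOC1, an apolipoprotein gene, was the member that rose, from 0.219 ± 0.0823 to 1.28 ± 0.429 CPM, a level near the expression filter. The list's median was -0.35 and its camera adjusted p was 0.00158, but with an estimated correlation the adjusted p was 0.116. Further genes among the 8 largest falls were DHRS3, a retinaldehyde reductase that fell from 41.9 ± 3.37 to 7.10 ± 0.891 CPM, and HR, a transcriptional corepressor that fell from 42.0 ± 7.13 to 7.98 ± 0.602 CPM. CRISPLD2, LXN, NREP and the endothelin receptor gene EDNRB fell by 1.51 to 1.70 on the log2 scale.

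**Figure D1:**
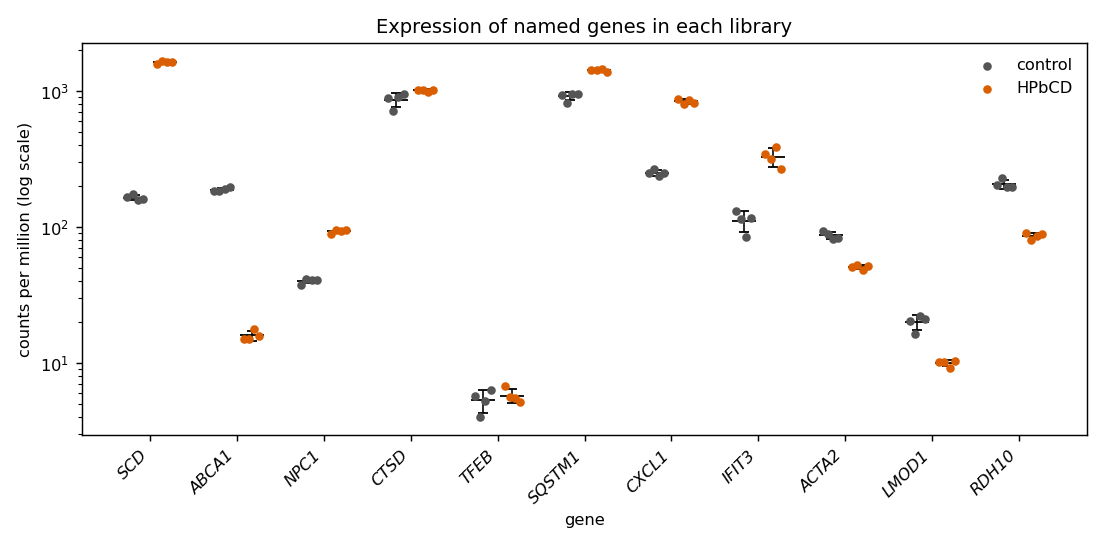
CPM on a log axis for 11 named genes in the 4 control libraries (grey) and the 4 HPbCD libraries (orange); points are libraries, horizontal bars are group means and error bars are SD. The groups are separate for SCD (164.8 against 1626 on average) and ABCA1 (188.7 against 15.9) and overlap for TFEB (5.31 against 5.76).

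TFEB itself (chromosome 6, 41683978 to 41736259) was measured at 5.31 ± 0.992 CPM in control and 5.76 ± 0.685 CPM in HPbCD cells, a difference smaller than the spread between replicates (log2 fold change 0.12 ± 0.13, edgeR adjusted p = 0.54). Over the 21 alternative settings its log2 fold change ran from 0 to 0.47. Its adjusted p ran from 0.0627 to 0.988, so TFEB did not pass in any. Its relatives TFE3 and MITF, named after their values were seen, had log2 fold changes of 0.11 ± 0.06 and -0.15 ± 0.07 and did not pass either. Their lowest adjusted p values over these settings were 0.055 and 0.0572. The 4 members of this list that did pass all rose: RRAGC, a GTPase of the lysosomal nutrient-sensing complex, by 1.58-fold, FLCN by 1.48-fold, and its partners FNIP1 and FNIP2 by 1.27-fold and 1.23-fold. FLCN and its partners hold TFEB in the cytoplasm. RNA levels do not show where the TFEB protein lies or how active it is. Of the list's 7 tested members the same 4 rose when adjusted over the list alone. Camera gave the list an adjusted p of 0.0204, which became an adjusted p of 0.129 with an estimated correlation, and the FNIP2 call was lost in 5 of 21 alternative settings. These were the fits without control replicate 4 (edgeR adjusted p = 0.0522) or HPbCD replicate 2 (0.0599), the length offset (0.205) and both TPM analyses (0.235 and 0.231).

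Part of the lysosomal genes rose. Of 40 hydrolases and activators, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.09. NEU1, a sialidase, rose 2.61-fold to 117.3 ± 3.10 CPM, and LIPA, the acid lipase that frees cholesterol from its esters, rose from 51.9 ± 5.63 to 108 ± 4.65 CPM; LIPA overlaps IFIT1, IFIT2 and IFIT3 on the opposite strand, and these also rose. TPP1 and GM2A rose by 0.34 and 0.32 on the log2 scale, CTSD, a major acid protease, rose 1.18-fold from 864 ± 102 to 1014 ± 19.5 CPM, and CTSB was the member that fell, by 0.16 on the log2 scale. Among 20 lysosomal membrane proteins 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.21. The cholesterol exporter NPC1 rose 2.33-fold from 40.1 ± 1.61 to 93.2 ± 2.66 CPM, the lipid phosphatase PIP4P1 2.22-fold, the cystine transporter CTNS 1.92-fold and NPC2 1.56-fold; NPC2, which this list also holds, is a soluble sterol carrier of the lysosomal lumen. LAMP1, an abundant membrane glycoprotein, had a log2 fold change of 0.12 ± 0.04 at an edgeR adjusted p of 0.0478, and LAPTM4A fell by 0.20 on the log2 scale. CTSB and LAPTM4A were named after their values were seen. Of 17 tested subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, 9 rose and none fell (12 and 1 adjusted over the list alone). Its examples ATP6V1B2, ATP6V0A1, ATP6V0C and ATP6AP1 rose 1.39-fold, 1.37-fold, 1.29-fold and 1.27-fold, and the median was 0.24.

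The hydrolase, membrane and vacuolar ATPase lists passed camera at adjusted p values of 0.0014, 1.33e-05 and 2.99e-05; with an estimated correlation the adjusted p values were 0.218, 0.0536 and 0.0237, so that the vacuolar ATPase call held. Without control replicate 2, in which the membrane list averaged 5.70 log2 CPM against 5.61 to 5.62 in the other controls, 17 membrane genes rose and 1 fell, 15 ATPase subunits rose and 1 fell, and 19 hydrolases rose and 4 fell. LAMP1 lost its call in 12 of 21 alternative settings, LAPTM4A in 9, CTSB in 5 and CTSD in 3, with the highest adjusted p values at 0.146, 0.123, 0.0577 and 0.0591. Among them were the fits without any 1 library except control replicate 2 for LAMP1, without control replicate 1 or any HPbCD library for LAPTM4A, without control replicate 4, HPbCD replicate 2 or HPbCD replicate 4 for CTSB, and without HPbCD replicate 1, 2 or 4 for CTSD.

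Autophagy genes went both ways: 8 of 41 rose and 6 fell (9 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.644, median 0.00). These shares are close to those over all tested genes, of which 2471 of 15400 rose and 2254 fell. SQSTM1, a receptor that carries cargo into autophagosomes, rose from 916.8 ± 62.7 to 1431 ± 28.9 CPM, a 1.56-fold change, and OPTN, another such receptor, rose 1.46-fold; SQSTM1 overlaps MGAT4B on the opposite strand (log2 fold change 0.37). VPS18, a tethering subunit, rose 1.36-fold, and GABARAPL1, of the autophagosome membrane, fell by 0.25 on the log2 scale. The GABARAPL1 call was lost with the length offset (adjusted p = 0.0969) and in both TPM analyses (0.137), and without control replicate 2, 9 members rose and 10 fell. BCL2, an inhibitor of apoptosis, was measured at 1.40 ± 0.243 CPM in control and 1.94 ± 0.549 in HPbCD cells and missed the threshold (edgeR adjusted p = 0.113, and 0.0319 without HPbCD replicate 2, in a range up to 0.355).

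Transcripts of inflammation and of the interferon response were higher with HPbCD. In the list of cytokines and NF-kappaB targets, 23 of 24 tested members rose, over all genes and adjusted over the list alone, with a median of 0.84. The neutrophil attractants CXCL1 and CXCL2 rose 3.36-fold, from 250.1 ± 11.6 to 839 ± 31.2 CPM, and 2.46-fold. The cytokine gene IL6 rose 3.25-fold from 94.6 ± 14.5 to 306.8 ± 18.5 CPM, the monocyte attractant CCL2 rose 1.75-fold from 59.3 ± 5.75 to 103.4 ± 3.64 CPM, and TNFAIP3, a feedback inhibitor of NF-kappaB, rose 1.79-fold. IL1A, named after its values were seen, was the member that missed the threshold, with a log2 fold change of 0.18 ± 0.13. Each of the 20 interferon response genes rose, also adjusted over the list alone, with a median of 1.20. The antiviral genes RSAD2 and IFIT2 rose 5.08-fold and 4.84-fold, IFIT3 rose 2.96-fold from 111.4 ± 19.2 to 329.2 ± 51.8 CPM, and the interferon regulator IRF7 rose 2.08-fold. RSAD2 overlaps CMPK2 on the opposite strand, whose log2 fold change was 1.84, so their separate values may be uncertain. The lists passed camera at adjusted p values of 4.71e-17 and 1.45e-12, but with an estimated correlation their adjusted p values were 0.0534 and 0.226. Summed over 13 immune cell markers, 12 of which stayed under 1 CPM in every library, expression was 4.23 ± 0.48 CPM in control and 2.78 ± 0.24 CPM in HPbCD cells; the tested member, CD14, fell from 3.54 ± 0.368 to 2.11 ± 0.193 CPM. The other 12 summed to 0.69 ± 0.13 CPM in control and 0.67 ± 0.19 CPM in HPbCD cells.

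Smooth muscle contractile genes changed in both directions. Of 19 tested members, 6 rose and 8 fell, over all genes and adjusted over the list alone; the median was -0.19 and the list did not pass camera (adjusted p = 0.38). ACTA2, the smooth muscle actin, fell from 87.0 ± 5.15 to 50.8 ± 1.72 CPM, 1.71-fold lower, and LMOD1, an actin filament nucleator, fell to 9.98 ± 0.522 CPM. MYOCD, the coactivator of the contractile program, fell by 1.08 on the log2 scale from 3.18 ± 0.252 CPM, whereas its partner SRF rose 1.39-fold. MYH11, the smooth muscle myosin heavy chain, did not pass the expression filter, at 0.401 ± 0.0767 CPM in control and 0.199 ± 0.103 in HPbCD cells. The MYOCD call was lost with the length offset, where its log2 fold change was -1.15 ± 0.40 against -1.08 ± 0.12 without it (adjusted p = 0.0597), and with both TPM analyses (-0.37 and -0.82, adjusted p = 0.211 and 0.197).

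Matrix genes were mixed as well. Of 33 collagen and elastic fibre genes 7 rose and 12 fell, over all genes and adjusted over the list alone, with a median of -0.07 and a camera adjusted p of 0.432. TNC, the adhesion-modulating glycoprotein tenascin C, rose from 1088 ± 96.0 to 2186 ± 135 CPM and COL8A1 rose 1.35-fold, while SPARC fell from 7052 ± 106 to 5411 ± 120 CPM and MFAP4 fell by 0.46 on the log2 scale. Control replicate 2 had the lowest mean of this list, and without it camera gave an adjusted p of 0.046 toward lower expression. Among 18 matrix proteases and inhibitors 7 rose and 3 fell, over all genes and adjusted over the list alone (median 0.07, camera adjusted p = 0.0775). The collagenase MMP1 rose 1.57-fold and the stromelysin MMP3 1.64-fold; TIMP3 fell from 753 ± 13.9 to 487.9 ± 8.61 CPM, and PLAT and ADAMTS5, named after their values were seen, fell by 0.31 and 0.18 on the log2 scale. ADAMTS5 lost its call in both TPM analyses, with adjusted p values of 0.0864 and 0.0858. The gelatinase MMP2 was measured at 2915 ± 267 CPM in control and 2942 ± 50.1 in HPbCD cells (edgeR adjusted p = 0.861).

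**Figure D2:**
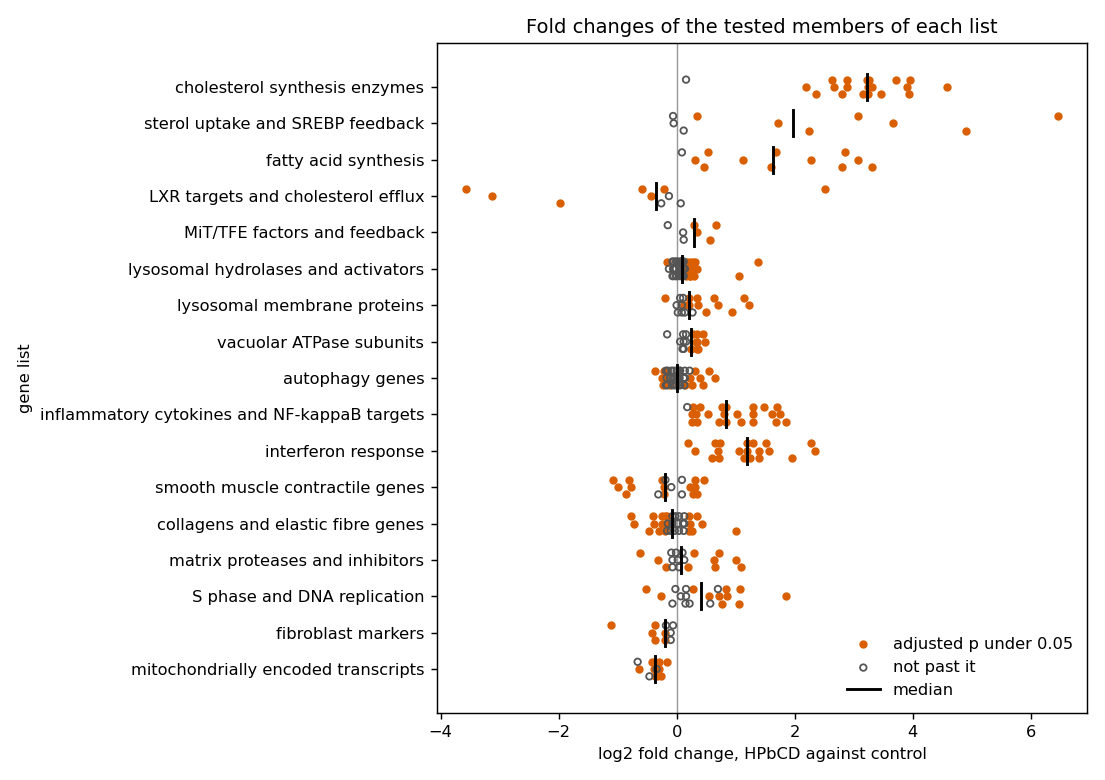
Log2 fold change, HPbCD against control, on the horizontal axis for each tested member of 17 gene lists on the vertical axis; filled orange points passed an edgeR adjusted p of 0.05, open grey points did not, and the black line is the list's median. The medians of the cholesterol synthesis, interferon response and collagen lists were 3.23, 1.20 and -0.07.

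Of 20 tested genes of S phase and DNA replication, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.42. The helicase subunits MCM2 and MCM5 rose 1.81-fold and 2.09-fold, from 7.39 ± 0.590 and 7.29 ± 0.740 CPM in control, and the replication factor CDC6 rose 2.10-fold from 1.53 ± 0.281 CPM. Thymidylate synthase, TYMS, fell from 21.6 ± 1.01 to 15.0 ± 0.958 CPM, and PCNA, the clamp of the DNA polymerases, fell by 0.27 on the log2 scale and was named after its values were seen. Camera gave an adjusted p of 0.00158, and with an estimated correlation an adjusted p of 0.179. CDC6 was just short of the threshold with the length offset (adjusted p = 0.0518) and in both TPM analyses (0.0512 and 0.0537).

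Mitochondrially encoded transcripts took a smaller share of the counts with HPbCD, 0.98 ± 0.03% against 1.26 ± 0.08% in control (two-sided exact permutation p = 0.0286, the smallest that 70 arrangements allow, and 0.0429 adjusted over the 3 composition measures). Of 13 such transcripts 10 fell (11 adjusted over the list alone) with a median of -0.36. MT-ND4 fell by 0.41, MT-CO1 by 0.39, and MT-CO3 and MT-CYB by 0.36 on the log2 scale. The list passed camera at an adjusted p of 4.69e-05, with an adjusted p of 0.293 under an estimated correlation. Control replicate 2 had the highest mean of this list (8.56 log2 CPM, other controls 8.09 to 8.26). Without it the mean log2 difference shrank from -0.351 to -0.258 (camera adjusted p = 0.000348). Fragment totals were lower with HPbCD, 27.3 ± 1.46 against 30.4 ± 2.25 M (difference -3.1, exact permutation p = 0.0286, adjusted p = 0.0429). This call was lost without control replicate 4 (difference -1.99, exact permutation p = 0.0857) and without any of the HPbCD libraries (-3.44 to -2.41, p = 0.0571 to 0.0857). The 10 most abundant genes held 17.1 ± 0.25% of the counts with HPbCD and 18.9 ± 1.01% in control (exact permutation p = 0.0571, adjusted p = 0.0571, and p = 0.0286 without control replicate 2).

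Markers of other cell types moved in different directions. Of 10 tested fibroblast markers 6 fell and none rose (7 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.00121 that became an adjusted p of 0.0534 with an estimated correlation. SCARA5 fell from 21.0 ± 2.71 to 9.69 ± 0.334 CPM, DCN from 4053 ± 76.6 to 3524 ± 81.6 CPM, MFAP5 by 0.36 and DPT by 0.42 on the log2 scale; DCN is also in the collagen and elastic fibre list. Of 10 tested endothelial markers 1 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.744, median -0.04, mean 0.03). VWF rose from 0.371 ± 0.156 to 1.35 ± 0.290 CPM, whereas TEK, TIE1 and PECAM1 fell by 0.38, 0.77 and 0.37 on the log2 scale from levels under 7 CPM. PECAM1 lost its call in 12 of 21 alternative settings, with adjusted p values up to 0.627; it kept it without control replicate 2 and without HPbCD replicate 1. The TIE1 call was lost in 4, with adjusted p values from 0.0547 without HPbCD replicate 3 to 0.93, and its log2 fold change was 0.07 with log2(TPM + 1). The epithelial markers that could be tested, KRT19 and CLDN4, both rose, from 9.58 ± 1.16 to 20.3 ± 0.839 CPM and from 0.604 ± 0.0781 to 1.44 ± 0.220 CPM.

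Of 34 lists with enough tested members, 17 passed camera, 13 toward higher and 4 toward lower expression. Besides those above, the heat shock proteins (median 0.20, adjusted p = 0.00779), the G2/M and mitosis genes (5 of 22 rose, 3 adjusted over the list alone, median 0.24, adjusted p = 0.00749) and the ATF4 and integrated stress response genes (median 0.07, adjusted p = 0.034) passed toward higher expression, and the nuclear genes of oxidative phosphorylation (median -0.13, adjusted p = 0.0257) toward lower. With an estimated correlation the adjusted p values of these lists were 0.129, 0.393, 0.331 and 0.532. The G2/M genes were expressed at low levels, averaging 0.15 ± 0.16 log2 CPM in control and 0.50 ± 0.21 with HPbCD. Their group means overlapped, since HPbCD replicate 4 (0.23) lay below control replicates 3 and 4 (0.24 and 0.32). Over all tested genes, 2471 of 15400 rose. The ATF4 list missed the threshold without control replicate 2 (adjusted p = 0.0575) or HPbCD replicate 4 (0.0508), and the oxidative phosphorylation list without HPbCD replicate 1 (0.076). For the oxidative phosphorylation list, control replicate 2 averaged 5.79 log2 CPM, against 5.56 to 5.64 in the other controls and 5.46 to 5.55 with HPbCD. Without that control the mean log2 difference shrank from -0.118 to -0.069 (camera adjusted p = 0.0466). The remaining 12 lists had camera adjusted p values from 0.152 to 0.893. Their medians were 0.13 for anti-apoptotic genes, 0.11 for macrophage-like foam cell markers, 0.09 for hypoxia and glycolysis, and 0.06 for both the TGF-beta response and the YAP/TAZ targets. Medians below 0 were -0.02 for pro-apoptotic genes and for caveolae and lipid rafts, -0.05 for endoplasmic reticulum chaperones, and -0.08 for both p53 and NRF2 targets. The osteochondrogenic and immediate early genes had medians of -0.06 and -0.01 with means of 0.11 and 0.03, and camera placed both toward higher expression. Without control replicate 2 the anti-apoptotic list passed, at an adjusted p of 0.0457.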

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

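The tests of immune cell RNA, of a rise carried by a single library, of depth and of a swapped label were chosen only after the result was seen. Each value below lies apart from the other 3 libraries of its group, judged by its gap to the nearest divided by the group's range. A flagged gap can be small in size where the range is narrow. List means were rounded before this test, which can raise the ratio. Of 292 groups of values, 26 met the bound, where chance gives about 14.6, and 13 of the 26 were in control replicate 2.

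Control replicate 2 had a mean fragment length of 288 bases against 352 to 357 in the other controls. Its mean log2 CPM was 5.70 for lysosomal membrane proteins (others 5.61 to 5.62), 9.81 for collagens and elastic fibre genes (9.95 to 9.97) and 7.22 for matrix proteases and inhibitors (7.32 to 7.34). It was low for SQSTM1 (823 CPM, others 937 to 954), MMP2 (2520, others 3016 to 3100), CRISPLD2 (7.54, others 8.43 to 8.44), MFAP4 (645, others 756 to 776) and SCARA5 (17.0, others 21.9 to 22.8). It was high for LIPA (60.3 CPM, others 48.8 to 49.3), MFAP5 (156, others 133 to 136), EDNRA (40.7, others 35.0 to 35.6) and PDE5A (480, others 394 to 401).

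Elsewhere among the controls, replicate 1 was high for PECAM1 (2.79 CPM, others 2.47 to 2.49), replicate 3 was low for the TGF-beta response list (6.59 log2 CPM, others 6.65 to 6.66), and replicate 4 was high for CLDN4 (0.721 CPM, others 0.558 to 0.578). Among the HPbCD libraries, replicate 1 was low for nuclear oxidative phosphorylation genes (5.46 log2 CPM, others 5.54 to 5.55). Replicate 2 was high for MVD (457 CPM, others 441 to 442) and TFE3 (131, others 123) and low for FNIP1 (36.6, others 38.6 to 38.9). Replicate 3 was low for CTSD (985 CPM, others 1022 to 1027) and the sterol uptake list (6.66 log2 CPM, others 6.69) and high for LIPA (115, others 105 to 106). Replicate 4 was high for EDNRB (7.62, others 6.47 to 6.64), DPT (7.35, others 6.57 to 6.69) and PDE5A (321, others 295 to 299).

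Control replicate 2 differed from every other control by a chi-square per degree of freedom of 19.4 to 26.9, against 2.09 to 3.85 between the other pairs within a group. Lower depth is argued against by its total of 29.3 M fragments, within the range of the other controls, and a swap with an HPbCD library by its cholesterol synthesis list, which lay 0.03 log2 CPM from the other controls. Across genes, which are not independent replicates, its difference from the other controls correlated with transcript GC content (Spearman rho = -0.669, against -0.124 to 0.136 for the same measure in the other controls), so GC bias in this library is a candidate explanation. The correlation with effective length was -0.105, between the bounds set beforehand, and stays open. No biological explanation was tested, since the labels do not set this library apart.

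The lysosomal lists combined were higher with HPbCD than other genes by a small factor (77 members, median 0.12, camera p = 2.14e-09 at the preset correlation). With all 8 libraries, most members did not pass on their own. Without control replicate 2 more passed: 19 hydrolases, 17 membrane proteins and 15 ATPase subunits rose, and 4, 1 and 1 fell. A few sterol-handling genes carrying the lists is argued against: without NPC1, NPC2 and LIPA the p was 3.57e-08 (0.000351 with an estimated correlation), and the median of the remaining 74 was 0.12, with a bootstrap SE of 0.023, against -0.015 for all genes. Bias from effective lengths that differ between libraries is argued against by the length offset, which left the median 0.166 above that of all genes, with an SE of 0.015. The offset cannot test a length-dependent difference between the groups that leaves effective lengths unchanged. A response to HPbCD may then be considered as a hypothesis, and other technical explanations were not tested.

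For the interferon and inflammatory lists, the tested members summed to 2426 ± 403 and 3371 ± 178 CPM in control and to 4911 ± 512 and 7011 ± 233 CPM with HPbCD. RNA of immune cells as the source of rises of this size is argued against by the immune markers, whose sum was not higher with HPbCD (difference -1.45 CPM, nearly all of it from CD14) and whose other 12, among them PTPRC, LYZ, TYROBP and LAPTM5, stayed under 1 CPM and differed by -0.01 ± 0.11 CPM (SE). These markers lie near the floor, so a trace of immune cells that leaves the rises unexplained is not excluded. A single library carrying the rise is argued against as well, since the smallest mean rise of either list with any library left out was 0.91 on the log2 scale. A response of the smooth muscle cells stays open as a hypothesis, as does any impurity of the HPbCD preparation, for which the data hold no test.

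For the counts of changed genes, chance in how these 8 libraries were grouped is argued against. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 4725 genes. This share is the smallest that 35 splits allow. The highest other split gave 1 gene. Each other split mixes HPbCD and control libraries, so the size of the gap adds no further evidence. For changes of at least 2-fold the real split gave 452 and the highest other 1. The splits do not test a difference between cultures that all libraries of a group would share.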

How the results depend on the processing

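The counts of list members without control replicate 2 and the comparison of fragment lengths were chosen after seeing the data. Across 21 alternative settings the number of changed genes ran from 3271 (log2(TPM + 0.1) in limma) to 6000 (without control replicate 2), within 1.5 times the main 4725, and each leave-one-out count lay between 3712 and 6000. The length offset gave 3519 genes, 3202 of them shared with the main test, and in no setting did a shared call have the opposite sign. The count of at least 2-fold changes was 216 with log2(TPM + 1), because that pseudocount shrinks fold changes of low genes, and 327 to 584 in the other settings. The number of lists past camera was 16 to 18 with a library left out, 4 with an estimated correlation and 29 with fry, which asks whether a list's genes move on balance and does not compare them with other genes.

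Of the 106 genes named, 93 kept their side of the threshold and their direction in every setting, apart from 4 sign changes or zero estimates of genes short of the threshold in both fits (MMP2, TFEB and MID1IP1). Of the 13 others, TIE1 turned from -0.77 to 0.07 with log2(TPM + 1), where its adjusted p was 0.912; the cause was not tested. The 7 calls lost with the length offset kept their direction there; the standard error was larger than in the main test for FNIP2, GABARAPL1, MYOCD, CDC6, TIE1 and PECAM1, and LAMP1 moved from 0.12 ± 0.04 to 0.10 ± 0.03. Leaving out a library gave differences in the library total of -3.63 to -1.99 M fragments. For the share of the 10 most abundant genes they were -2.23 to -1.52 percentage points. The mitochondrial share kept an exact permutation p of 0.0286 with each library left out. Fewer arrangements therefore do not by themselves remove a call, and the cause of the changed calls was not tested. With the replicate number as a block (replicate block), 4333 genes changed, 452 at least 2-fold, and 17 lists passed. Deviations of samples with the same number correlated at -0.061 to 0.006, against -0.049 to 0.1 for different numbers. The numbers thus gave no sign of pairing, though a weak pairing is not excluded, and no sample pairing was used. APOC1 and VWF could be tested in 20 of the 21 settings. Depth limits genes near the filter, such as APOC1, CDC6 and TIE1.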

Other observations

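The metallothionein and cyclic nucleotide lists below were assembled only after the results were seen, and so was the retinoid list, though the test of its remaining members was set beforehand. Metallothioneins, small proteins that bind zinc and copper, were higher with HPbCD. The abundant member MT2A rose from 142.4 ± 24.2 to 272.7 ± 12.2 CPM and MT1G rose from 0.305 ± 0.114 to 2.09 ± 0.501 CPM (SD, n = 4). Of 4 tested members not looked at when the list was drawn up, 3 rose, MT1E, MT1G and MT1X (camera p = 0.00944, and p = 0.0471 with an estimated correlation). These genes are close copies of each other, so the division of reads between them is uncertain. The 4 members are thus not independent of those already seen, and their camera test adds little separate evidence. Some genes of cyclic nucleotide signalling and contraction regulation were lower. EDNRA, an endothelin receptor, fell from 36.7 ± 2.68 to 22.8 ± 0.87 CPM and PDE5A, the phosphodiesterase that breaks down cyclic GMP, fell from 418.7 ± 41.2 to 302.9 ± 11.9 CPM. Of 15 tested members not looked at beforehand, 6 fell and none rose, with a median of -0.26 (camera p = 0.000321, and p = 0.00917 with an estimated correlation). Among those that did not pass were ADCY3, ADCY6, PDE4B and PDE4D, with log2 fold changes of -0.1 to 0.04. PRKG1 (-0.19) and GUCY1B1 (-0.34) did not pass either.

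Retinoid enzymes and binding proteins were among the largest falls, which led to the hypothesis that retinoid-handling genes fell as a set. Besides DHRS3, the alcohol dehydrogenase ADH1B fell from 55.3 ± 2.99 to 19.5 ± 0.883 CPM and the retinol dehydrogenase RDH10 fell from 206.8 ± 16.5 to 86.1 ± 4.57 CPM. Among 18 tested members whose values had not been looked at, 6 fell and 1 rose, with a median of -0.25 and a camera p of 0.0113 toward lower expression; with an estimated correlation the p was 0.181. The retinoic acid receptor RARB fell from 1.78 ± 0.149 to 0.282 ± 0.128 CPM and the retinoic acid hydroxylase CYP26B1 from 1.97 ± 0.206 to 0.445 ± 0.112 CPM. ALDH1A3, which makes retinoic acid, went the other way, from 46.8 ± 2.34 to 76.0 ± 3.25 CPM. Lower retinoid signalling may go with HPbCD in these cells, but the set test rests on the preset correlation and the files hold no measure of retinoids.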
